A study of Homo sapiens with 8 samples.

How the data were processed

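Total RNA of 8 tumours, 4 labelled uncastrated and 4 labelled castrated, had been labelled with biotin from 200 ng per tumour with a 3' in vitro transcription kit, per the labels' protocols, and hybridised to 1 array each. The deposited intensity values are linear probe set intensities, which the authors made with RMA per the submitters' processing notes; the version is not given in the sources used here. RMA gives log2 values, and the deposited values are not on that scale, so how they were returned to a linear scale is unknown. Values lay between 2.19 and 18189, with medians per array of 23.2 to 26.5. No detection calls and no scan dates were used here, so dim probe sets were kept and no batch could be taken from the files. The design text and the probe set identifiers name different arrays, as described in the report; genes were named from the platform table that matches the identifiers.

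Of 54675 probe sets, 62 controls were left out. Of the rest, 41091 had 1 gene symbol, 1801 had several and 11721 were unnamed, and only those with 1 symbol were used. Of these, 41037 matched a gene of the RefSeq annotation of GRCh38.p14, used for names only, and 0 symbols needed updating. A gene with several probe sets was represented by the one with the highest mean over all 8 arrays, which left 19775 genes. Some genes of the lists are not reported here.

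Log2 was taken of the deposited intensities with no further scaling, no pseudocount and no filter. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, default settings, no covariates), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Groups came from the intervention label. Replicate numbers are not shared between groups, so no pairing was fitted. On simulated data for this comparison, with 19775 genes, 39% of genes changed by 1 on the log2 scale and 94% of genes changed by 3 were recovered, 6.99% of calls were unchanged genes and 0 genes were called when none was changed. The simulated values were normal and independent between genes and arrays, with no outlying and no nearly alike arrays. These rates therefore need not hold for the real arrays.

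Before the data were examined, 28 lists with 640 genes were fixed, of which 579 were measured. They cover androgen-induced, androgen-repressed, steroid, nuclear receptor, neuroendocrine, cell cycle, cholesterol, fatty acid, hypoxia, oxidative phosphorylation, interferon, stress, immediate early, epithelial, mesenchymal, growth factor, Wnt, stem cell and apoptosis genes, and markers of 9 other cell types or secretions. Each list was tested with camera at a preset correlation, with camera at an estimated correlation, with fry, and by an exact permutation test on the mean log2 value per tumour. Also fixed then was the rule for named genes: the 12 largest rises and 12 largest falls among called genes without overlap between groups (leaving out non-coding, pseudogene, open reading frame and FAM names), the 2 members of each list with the smallest p, or 4 where the list passed, and a set of reference genes. This gave 98 genes. Lists of markers of prostate, lung, liver, colon, thyroid, breast, urothelium and kidney, of abundant genes, and of YAP and TAZ target genes and actomyosin genes were added after the data were seen.

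Alternatives fixed beforehand were centring on the median or the 75th percentile, a further quantile normalization, filters on dim genes, other ways of handling several probe sets, eBayes with trend and robust settings, array weights, other thresholds, the title suffix P (on 3 uncastrated and 1 castrated tumour, meaning not given) as a block and within each suffix, tumour 93 moved to the uncastrated group, and leaving out each array. Averaging tumours 90, 91 and 93, leaving out 57P and 65P together, and list tests within each suffix were added later. All tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 or in R.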

Results

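Transcript levels were measured in 8 tumours labelled as orthotopic xenografts of LNCaP, a human prostate cancer line whose growth responds to androgen. Per the labels, the cells were grown under the skin of male nude mice, some hosts were castrated once tumours had reached 10 mm, and regrown tumours were then passaged in the prostate of intact or castrated hosts. The 4 tumours labelled uncastrated carry the numbers 75, 51P, 65P and 66P. The 4 tumours labelled castrated carry the numbers 90, 91, 93 and 57P. The free-text description of castrated tumour 93 calls it uncastrated, while its title, source name and intervention label call it castrated. The labels do not say whether tumours of a group descended from separate injected tumours, so the p-values measure only the spread between these samples. The deposited values were linear probe set intensities from 1 array per tumour, with medians per array between 23.2 and 26.5. The series design text names a Human Gene 2.0 ST array, whereas the probe set identifiers and the platform table are those of the U133 Plus 2.0 array. The number of arrays, 4 per group, limits the precision.

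The comparison asked which transcripts differed between tumours kept in castrated hosts and tumours kept in intact hosts. In the castrated group KIT, a receptor tyrosine kinase, rose 32.9-fold and TNFSF10, the death ligand TRAIL, rose 18.8-fold. SLC6A14, an amino acid transporter, rose 13.3-fold. MSN, which encodes the membrane-cytoskeleton linker moesin, was 56.3-fold lower by the probe set used, and DPYSL2 was 12.8-fold lower. The transketolase-like gene TKTL1 and ANKRD1, a target of the YAP and TAZ coactivators, fell to values near the floor of the arrays, where a fold is not well defined. The secretory kallikrein KLK3, the gene of prostate-specific antigen, was at 6.44 ± 0.34 in uncastrated and 6.52 ± 0.21 in castrated tumours (log2 intensity, SD, n = 4 each), a difference within the spread between tumours.

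Among 19775 genes, 87 rose and 156 fell in castrated tumours (limma, Benjamini-Hochberg adjusted p under 0.05). In all 243 of them the 4 castrated arrays lay wholly above or wholly below the 4 uncastrated arrays. Such separation was present in 8.35% of all genes. Chance gives 2.86% if all arrays are independent tumours. It gives a higher share if castrated 90, 91 and 93, or uncastrated 65P and 66P, were 1 tumour. Of the called genes, 70 rose and 141 fell by at least 2-fold. The count depended on single arrays: it was 1711 without castrated tumour 57P, 435 without uncastrated 51P, 31 without uncastrated 65P, 51 without uncastrated 66P, 22 without castrated 90, 41 without castrated 91 and 79 without castrated 93. It was 1 with castrated 93 put with the uncastrated tumours, and 0 with castrated 90, 91 and 93 averaged into 1 sample, an alternative chosen after the data were seen (limma; 1532 at unadjusted p under 0.05). It was 192 with the title suffix P, carried by 3 uncastrated and 1 castrated tumour, as a block, and 125 of the 243 genes were among these in the same direction. Within titles with the suffix 7527 genes passed and within titles without it 823, each with a lone array in 1 group that was assumed to vary like the others. All 243 genes were also called, in the same direction, without 57P, but the share of lower genes among the calls was 34.3% there against 64.2% with all arrays, and with arrays centred on their 75th percentile 150 genes rose and 108 fell.

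The largest rise was that of KIT, from 4.22 ± 1.36 to 9.25 ± 0.61 (log2 intensity, SD, n = 4), a log2 change of 5.04 with a standard error of 0.62 and a limma adjusted p of 0.0113. TNFSF10 followed with a log2 change of 4.23 (standard error 0.44, limma adjusted p = 0.00623). SLFN11, a DNA damage response gene, rose by 3.68 on the log2 scale, the carboxypeptidase-like gene CPVL by 3.48, CYBA, a subunit of the phagocyte NADPH oxidase, by 3.42 and the transcription factor FOXQ1 by 3.36. GSPT2, a translation termination factor, also rose by 3.36, with the weakest adjusted p of the 12 largest rises (0.0453). HPGD, which breaks down prostaglandins, rose by 3.18, the chemokine receptor ACKR3 by 3.01, the interferon-induced OAS1 by 2.95 and ARID5B by 2.92. SLC6A14 was at 10.9 in castrated 57P and between 8.70 and 9.79 in the other castrated tumours.

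Among the falls, MSN fell by 5.82 on the log2 scale, from 10.1 ± 0.51 to 4.31 ± 1.04 (SD, n = 4, limma adjusted p = 0.00424). TKTL1 fell by 5.39 and ANKRD1 fell by 4.90. DPYSL2, a regulator of microtubules, fell by 3.68 from 10.7 ± 0.48 to 7.07 ± 0.58 (SD, n = 4). The RNA-binding gene RBMS3 fell by 3.45, the transcription factor MYBL1 fell by 3.25, the receptor ROR1 fell by 3.19 and the endothelial junction gene HEG1 fell by 3.06. TRNP1 and the nuclear envelope gene SYNE1 fell by 3.06, the galactosyltransferase UGT8 fell by 3.04 and the collagen gene COL1A1 fell by 3.01. Other probe sets of some genes went the other way: only 1 of 2 for MSN, 1 of 3 for MYBL1, 1 of 2 for TRNP1, 3 of 5 for COL1A1, 5 of 7 for RBMS3 4 of 5 for SYNE1, 3 of 5 for TGFB2 and MYLK and 2 of 3 for ITGB2 had the sign of the probe set used. Of the 62 named genes not past the threshold 14 had probe sets of both signs, such as WFDC2 with 1 of 3. With the probe sets of each gene averaged, the log2 changes were 0.76 for ARID5B, 1.10 for ACKR3 and 1.79 for CYBA among the rises, and -2.76 for MSN, -1.46 for TRNP1, -1.32 for COL1A1, -1.22 for RBMS3 and -0.87 for MYBL1 among the falls. HPGD, MYBL1, SYNE1, UGT8, TRIB3, KLF6, TGFB2 and ITGB2, 8 of the 36 named genes past the threshold, were then no longer past it, and for 18 of the 36 the change was more than 1.5 times smaller. Of the 24 genes with the largest changes 5 (CPVL, GSPT2, ACKR3, TKTL1 and ANKRD1) lay below the lower quartile of probe sets on at least 3 arrays of the dimmer group. In castrated 90, 91 and 93 TKTL1 was at 2.55 to 2.95 and ANKRD1 at 2.64 to 2.65, so the sizes of these changes rest on values near the floor. With the probe set used here, 11 of the 36 stayed past the threshold whichever array was left out: TNFSF10, CYBA, FOXQ1, ARID5B, MSN, ANKRD1, DPYSL2, ROR1, HEG1, COL1A1 and FBN1. KIT, SLC6A14, TKTL1 and OAS1 were among those that did not.

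**Figure D1:**
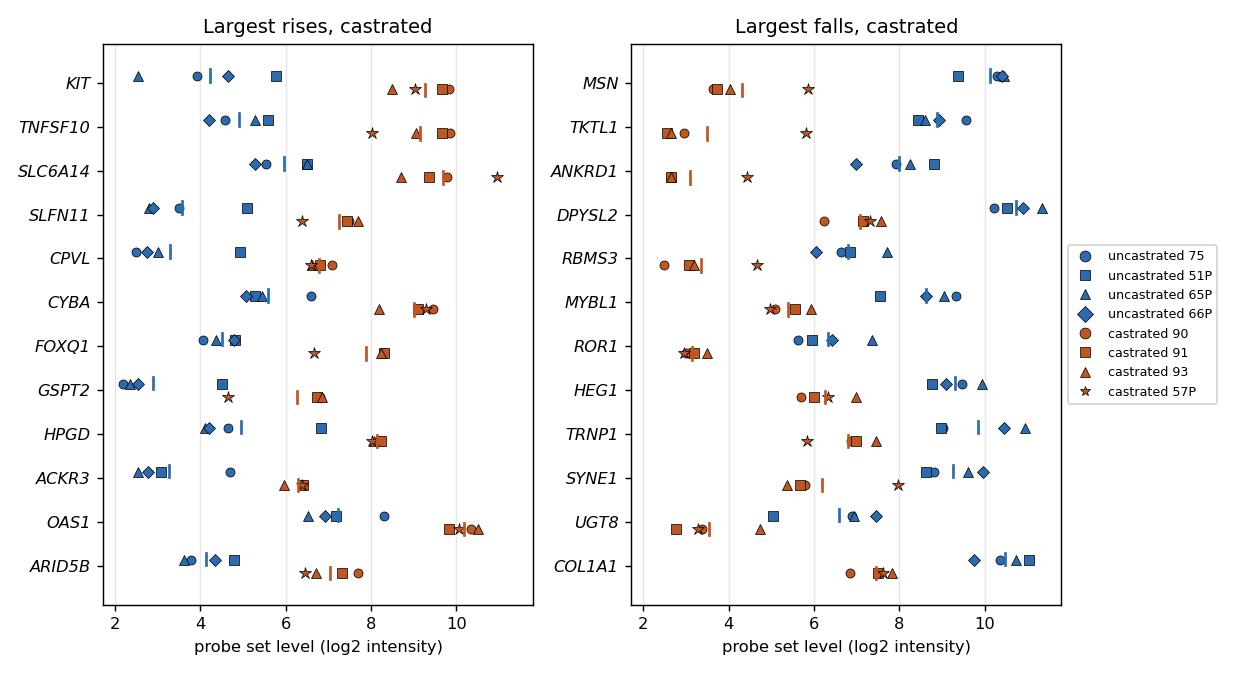
Log2 probe set intensity (horizontal axis) of the 12 genes with the largest rise and the 12 with the largest fall, with 1 point per array (blue, uncastrated; orange, castrated) and a vertical tick at each group mean. The groups do not overlap for any of these genes, and KIT lies at 2.54 to 5.78 in uncastrated and 8.49 to 9.84 in castrated tumours.

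Several genes typical of prostate luminal cells had low intensities on most arrays of both groups, a check chosen after the values were seen. Intensities of different probe sets depend on probe affinity, so low and high are only rough ranks here. KLK2, a kallikrein, was at 4.75 ± 0.09 and 4.89 ± 0.54 (log2 intensity, uncastrated and castrated, SD, n = 4), with castrated 57P at 5.69, and FOLH1, prostate-specific membrane antigen, at 3.39 ± 0.12 and 3.57 ± 0.44. The homeobox gene HOXB13 was at 4.45 ± 0.35 and 4.65 ± 0.23, and the prostate transporter SLC45A3 at 4.75 ± 0.29 and 4.53 ± 0.18. Others lay above the middle of all genes: SPDEF was at 6.96 ± 0.32 and 7.25 ± 0.60, TMPRSS2 at 6.55 ± 0.48 and 7.26 ± 0.57, KLK4 at 6.36 ± 0.21 and 6.55 ± 0.23 and STEAP1 at 5.21 ± 0.82 and 7.44 ± 0.94 (SD, n = 4), the last 3 at percentiles of mean level of 67.2, 61.0 and 59.1. Some genes of lung epithelium had high intensities: the protease NAPSA was at 10.5 ± 0.27 in uncastrated tumours, the surfactant protein gene SFTPB at 10.8 ± 2.60 and the surfactant-associated gene SFTA3 at 10.3 ± 0.72. In castrated tumours 90, 91 and 93, NAPSA lay between 5.96 and 7.90, and in castrated 57P it was at 11.1. NKX2-1, SFTA2 and LPCAT1, also on the lung list, were at 8.25 ± 0.41, 9.98 ± 0.78 and 11.6 ± 0.38 in uncastrated tumours (SD, n = 4). In castrated 90, 91 and 93 these lay at 6.21 to 6.74, 5.80 to 8.59 and 9.02 to 9.76, and SFTA3 at 6.62 to 7.57. In castrated 57P the same genes were at 8.58, 11.7, 11.4 and 9.56. LAMP3, on the same list, went the other way, at 8.01 to 8.41 in castrated 90, 91 and 93 and 5.22 in 57P. Other lung genes were low, with SCGB1A1, ROS1, CLDN18, SCGB3A1 and AGER at percentiles of mean level of 18.4, 13.3, 28.5, 36.4 and 41.4. The fibrinogen genes FGG, FGB and FGA, listed for liver, were high as well, at 11.6, 11.2 and 8.74 in uncastrated tumours. Abundant genes of all cells were high, with GAPDH at 13.4 ± 0.10 and 13.3 ± 0.10. Group names are used below as the labels give them.

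**Figure D2:**
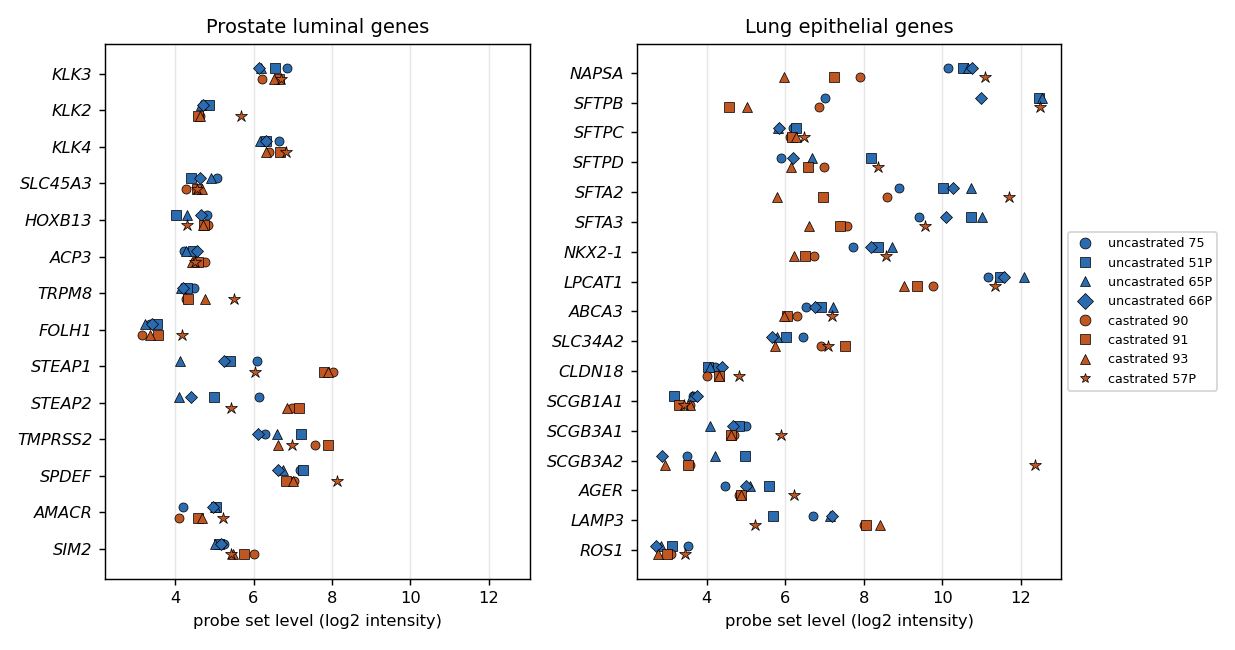
Log2 probe set intensity (horizontal axis) of 14 prostate luminal genes and 17 lung epithelial genes, with 1 point per array (blue, uncastrated; orange, castrated). KLK3 stays between 6.15 and 6.86 on all arrays, while SFTPB is highest on uncastrated 65P, castrated 57P and uncastrated 51P and lies at 4.57 on castrated 91.

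Castrated tumour 57P stood apart from the other arrays. Its mean correlation with them was 0.919, against 0.957 to 0.967 for the others, and its bioB hybridisation spike read 791 against 201 to 399. Its lower quartile of intensity was 10.6, against 8.52 to 9.05 elsewhere, and its upper quartile 68.3, against 78.5 to 87.1. Castrated 90, 91 and 93 were nearly alike, with pairwise correlations of 0.993 to 0.995. Uncastrated 65P and 66P were also close, with a correlation of 0.988, against 0.967 to 0.976 for the other uncastrated pairs. The ACTB ratio of 3' to 5' probe sets, a sign of RNA integrity, was 17.1 in uncastrated 65P and 9.04 in uncastrated 66P, against 2.53 to 3.84 on the other arrays.

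For the gene lists, the question was whether members of a list fixed before the data were examined stood apart from other genes. Of 28 lists, 8 passed limma's camera test with a preset correlation (adjusted p under 0.05). Androgen-repressed, interferon-stimulated, hypoxia and glycolysis, and stem cell lists were higher in castrated tumours. Cell cycle, cholesterol synthesis, mesenchymal transition and smooth muscle lists were lower. With an estimated correlation 0 lists passed, the smallest adjusted p being 0.451, and 2 had an unadjusted p under 0.05. By fry, which asks only whether a list moved one way on balance, 2 lists passed, androgen-repressed and stem cell. With the title suffix as a block 3 passed camera, cell cycle, mesenchymal transition and stem cell. Without 57P, 1 list passed camera, hypoxia and glycolysis (adjusted p = 0.0187).

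Among 34 androgen-induced genes 2 rose and 0 fell: STEAP4, a metalloreductase, rose 6.35-fold (limma adjusted p = 0.0274) and HPGD rose 9.07-fold. Adjusted over the list alone, 6 rose and 3 fell, and the camera adjusted p was 0.312. Of 15 androgen-repressed genes 1 rose, the chemokine receptor ACKR3, and 0 fell (2 rose adjusted over the list alone). IGFBP3, a binder of insulin-like growth factors, was 4.53-fold higher without passing (limma adjusted p = 0.0585), and CCN3 and UGT2B15 were both 1.28-fold higher without passing. The list had a median log2 change of 0.26 (camera adjusted p = 0.0285, and adjusted p = 0.451 with an estimated correlation). Its call was lost without castrated 57P (adjusted p = 0.221, median log2 change 0.27) and without uncastrated 51P (0.0745, median 0.29), where the median was as large as with all arrays, and over 23 alternatives the adjusted p ran from 0.0080 to 0.451. FKBP5, an androgen- and glucocorticoid-induced chaperone, was at 10.7 ± 1.38 and 9.80 ± 0.29 (SD, n = 4, limma adjusted p = 0.591), and the protease TMPRSS2 at 6.55 ± 0.48 and 7.26 ± 0.57 (limma adjusted p = 0.411). Uncastrated 75 held FKBP5 at 8.73, against 11.1 to 11.9 in the other uncastrated tumours and 9.52 to 10.1 in castrated tumours.

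In the list of steroid synthesis and androgen metabolism 0 of 28 members passed in limma (1 higher and 1 lower at an unadjusted p under 0.05), and the camera adjusted p was 0.759. SULT2B1, a sulfotransferase, and RDH5, a retinol dehydrogenase, had the smallest p, with log2 changes of 0.84 and -0.60. In the list of nuclear receptors and cofactors 0 of 22 passed in limma, with 1 higher and 1 lower at an unadjusted p under 0.05 (camera adjusted p = 0.689). There VDR, the vitamin D receptor, and RORA had log2 changes of -0.47 and 1.13. The glucocorticoid receptor NR3C1 was at 10.2 ± 0.27 and 10.3 ± 0.91 (SD, n = 4), with 57P at 8.99. Neuroendocrine markers had 0 of 27 members past limma's test, with 2 higher and 6 lower at an unadjusted p under 0.05 (2 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.759). SOX2 and CHGB, a granin, were 1.68-fold and 4.40-fold higher without passing, both at a limma adjusted p of 0.0909. The granin CHGA was low, at 3.77 ± 0.13 and 4.01 ± 0.17, and the neuronal enolase ENO2 was at 7.22 ± 0.18 and 6.75 ± 0.15 (log2 intensity, SD, n = 4), neither past the test.

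Among 40 cell cycle genes 0 passed singly in limma, 4 were lower at an unadjusted p under 0.05, and 33 had a lower mean in castrated tumours. The median log2 change was -0.32 (camera adjusted p = 0.0116, and adjusted p = 0.818 with an estimated correlation). The mitotic genes CDC20, TOP2A, CENPF and BIRC5 were 2.06-fold, 2.18-fold, 1.77-fold and 1.41-fold lower, none past the test, and the proliferation marker MKI67 was 1.47-fold lower (limma adjusted p = 0.541). The list's score was 7.54 in castrated 57P, the array that stood apart, against 8.48 to 8.68 in the other castrated tumours. Among uncastrated tumours it was 8.95 in 65P and 8.98 in 66P, the arrays with the highest ACTB ratios, and 8.42 in 75 and 8.13 in 51P. The call was lost without 57P (adjusted p = 0.597, median log2 change -0.13), without uncastrated 65P (0.0505, median -0.20) and without uncastrated 66P (0.0878, median -0.21), the median was -0.50 without uncastrated 51P, and over 23 alternatives the adjusted p ran from 2.38e-06 to 0.834. Among titles without the suffix P, where uncastrated 75 is the lone array of its group, the median log2 change was 0.08.

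Cholesterol synthesis had 0 of 19 members past limma's test, with 1 higher and 5 lower at an unadjusted p under 0.05 (2 lower adjusted over the list alone) and a median log2 change of -0.23. Its camera adjusted p was 0.0319, and the adjusted p was 0.724 with an estimated correlation. The squalene epoxidase SQLE was 2.95-fold lower (limma adjusted p = 0.0515), and MSMO1, HMGCS1 and DHCR7, enzymes of the same pathway, were 1.82-fold, 1.78-fold and 1.80-fold lower without passing. The median was -0.12 without uncastrated 51P and -0.34 without uncastrated 75. The call was lost without uncastrated 51P (adjusted p = 0.264), uncastrated 65P (0.0715), castrated 91 (0.0817) or castrated 57P (0.101), and after a further quantile normalization (0.28), and over 23 alternatives the adjusted p ran from 0.00426 to 0.817. Fatty acid synthesis had 0 of 18 members past limma's test, with 3 lower at an unadjusted p under 0.05 (camera adjusted p = 0.0861), with ACSL4 2.29-fold and ACLY 1.80-fold lower without passing.

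Of 28 hypoxia and glycolysis genes 1 rose, ANKRD37, a target of hypoxia-inducible factor, by 3.06-fold (limma adjusted p = 0.00841), with a log2 change of 1.61, and 0.97 with its probe sets averaged. The median log2 change of the list was 0.29 (camera adjusted p = 0.0319, and adjusted p = 0.724 with an estimated correlation). ALDOC, the glucose transporter SLC2A1 and the prolyl hydroxylase EGLN3 were 1.48-fold, 2.33-fold and 3.10-fold higher without passing. The score was 9.19 in uncastrated 65P and 8.98 in uncastrated 66P, the arrays with the highest ACTB ratios, 9.64 in uncastrated 75, 9.54 in uncastrated 51P and 9.35 to 9.89 in castrated tumours. The median was 0.17 without uncastrated 66P and 0.19 without castrated 91. It was only 0.03 with the title suffix as a block (camera adjusted p = 0.409). Among titles without the suffix, where uncastrated 75 is the lone array of its group, it was 0.04. The call was lost without uncastrated 65P (adjusted p = 0.054), uncastrated 66P (0.228), castrated 91 (0.0857) or castrated 93 (0.101), and over 23 alternatives the adjusted p ran from 0.00426 to 0.823. Oxidative phosphorylation had 0 of 28 members past limma's test, with 2 higher and 1 lower at an unadjusted p under 0.05, and a camera adjusted p of 0.953. Its members NDUFS7 and NDUFV2 had log2 changes of -0.85 and 0.67.

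Of 31 interferon-stimulated genes 2 rose, OAS1 by 7.73-fold and the exonuclease ISG20 by 2.59-fold (limma adjusted p = 0.0103 and 0.0393), and 5 rose adjusted over the list alone. IFIT5 and MX1 were 2.04-fold and 3.08-fold higher without passing. The list's median log2 change was 0.39 (camera adjusted p = 0.0187, and adjusted p = 0.781 with an estimated correlation). The highest score of all arrays was that of uncastrated 75, at 7.33, while the other uncastrated tumours lay at 5.79 to 6.33 and the castrated tumours at 6.55 to 7.07. The median was 0.80 without uncastrated 75 and 0.13 without uncastrated 51P. The call was lost without uncastrated 51P (adjusted p = 0.264) and without castrated 57P (0.148), where the median was 0.41. Among titles without the suffix P, where uncastrated 75 is the lone array of its group, the list passed camera in the other direction, with a median log2 change of -0.20 (adjusted p = 0.0138). Over 23 alternatives the adjusted p ran from 1.1e-05 to 0.781. In the unfolded protein and amino acid stress list 1 of 26 members fell, TRIB3, a pseudokinase, which was 2.07-fold lower (limma adjusted p = 0.0207), and PSAT1 was 2.03-fold lower without passing. That list's camera adjusted p was 0.848. Of 23 immediate early genes 1 fell, KLF6, which was 2.17-fold lower (limma adjusted p = 0.040), CCN1 was 3.21-fold lower without passing, and the camera adjusted p was 0.953.

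Of 22 mesenchymal transition genes 3 fell and 0 rose. The growth factor TGFB2 was 3.88-fold lower, the receptor kinase AXL 4.48-fold lower and the intermediate filament gene VIM 4.42-fold lower (limma adjusted p = 0.0207, 0.0226 and 0.0314). LOXL2 was 3.06-fold lower without passing, and only 1 of its 4 probe sets had that sign. The list's median log2 change was -0.14 (camera adjusted p = 0.0288, and adjusted p = 0.724 with an estimated correlation). The median was -0.03 without uncastrated 75, -0.09 without castrated 91, -0.25 without castrated 93 or 57P, -0.27 without uncastrated 65P and -0.29 without uncastrated 66P. That call was lost without uncastrated 75 (adjusted p = 0.19), uncastrated 51P (0.0745), castrated 90 (0.0547) or castrated 57P (0.0567), and over 23 alternatives the adjusted p ran from 1.63e-05 to 0.724. Among 21 epithelial markers 0 passed in limma, with 4 higher at an unadjusted p under 0.05 (camera adjusted p = 0.131), with RAB25 3.13-fold and ELF3 2.14-fold higher. Basal epithelium had 0 of 7 members past limma's test, with 1 higher and 1 lower at an unadjusted p under 0.05 (camera adjusted p = 0.953), with log2 changes of -1.27 for DST and 1.93 for TRIM29. Without castrated 57P these changes were -0.77 and 2.57.

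Stem cell markers had 0 of 16 members past limma's test over all genes, 1 adjusted over the list alone and 3, all higher, at an unadjusted p under 0.05. SOX2, the integrin ITGA2, SOX9 and ALDH1A1 were 1.68-fold, 2.41-fold, 2.52-fold and 6.37-fold higher without passing. ALDH1A1 varied widely: it was at 8.45 in uncastrated 51P, 2.79 to 4.76 in the other uncastrated tumours and 5.43 to 8.62 in castrated tumours. The list's median log2 change was 0.31 (camera adjusted p = 0.0187, and adjusted p = 0.451 with an estimated correlation). The call was lost without 57P (0.0567), where the median was also 0.31, and over 23 alternatives the adjusted p ran from 0.00958 to 0.451. Among 28 growth factor receptors and ligands 1 rose, KIT, and ERBB3 was 2.30-fold higher without passing (limma adjusted p = 0.055, and 0.183 for the list in camera). Of 20 Wnt pathway genes 1 fell, DKK3, an antagonist family member, which was 4.76-fold lower (limma adjusted p = 0.0236), with a log2 change of -2.25, and -0.93 with its probe sets averaged. NOTUM was 1.91-fold higher without passing, and the list had a camera adjusted p of 0.237. Of 24 apoptosis regulators 1 rose, TNFSF10, BAX was 1.63-fold lower without passing, and the list had a camera adjusted p of 0.863.

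The mean scores of 9 lists of other cell types and secretions lay between 4.03 and 6.09 on the log2 scale. The hosts were mice and the probe sets are named for human genes, so these lists need not measure host tissue. Of 20 fibroblast genes 2 fell, FBN1, the fibrillin gene, 7.13-fold lower, and COL1A1, 8.08-fold lower (limma adjusted p = 0.00424 and 0.00623), while the camera adjusted p was 0.457. Of 12 smooth muscle genes 1 fell, MYLK, myosin light chain kinase, 3.74-fold lower (limma adjusted p = 0.0265), with a log2 change of -1.90, and -0.88 with its probe sets averaged, and CALD1, ACTA2 and TPM2 were 2.09-fold, 2.00-fold and 1.66-fold lower without passing. The smooth muscle list had a median log2 change of -0.26 (camera adjusted p = 0.0411, and adjusted p = 0.724 with an estimated correlation). The median was -0.09 without uncastrated 75, -0.15 without castrated 90 and -0.45 without uncastrated 65P. That call was lost without uncastrated 75 (adjusted p = 0.226), uncastrated 51P (0.143), castrated 90 (0.106), castrated 91 (0.0869) or castrated 57P (0.0642), and over 23 alternatives the adjusted p ran from 0.0012 to 0.823. The smooth muscle call was also lost with probe sets averaged (camera adjusted p = 0.089, median log2 change -0.10). The same held with the probe set of highest interquartile range (0.0795) and the milder filter on dim genes (0.0552), but not with the stricter filter (0.0218). Of 17 macrophage and leukocyte genes 1 fell, the integrin ITGB2, 2.91-fold lower (limma adjusted p = 0.0398), with LYZ at a log2 change of 0.39 and a camera adjusted p of 0.759 for the list. Endothelium (CDH5 1.52-fold and EGFL7 1.53-fold higher), skeletal muscle (TNNI2 1.74-fold and ATP2A1 1.35-fold higher), erythrocyte (AHSP 1.14-fold and ALAS2 1.18-fold higher), adipocyte (LPL 1.15-fold and RETN 1.31-fold higher) and glandular secretion (MSMB 4.35-fold and WFDC2 3.08-fold higher) had 0 members past limma's test. At an unadjusted p under 0.05, 2 endothelial genes were higher and 1 lower, 3 secretion genes were higher, and 0 members of the remaining lists passed. Their camera adjusted p were 0.178, 0.503, 0.849, 0.503 and 0.114. The skeletal muscle, endothelium, macrophage, erythrocyte, adipocyte and glandular secretion scores were highest in 57P, the array that stood apart, at 4.53, 4.85, 4.89, 5.54, 4.88 and 6.17. Without 57P the median log2 change of the secretion list was 0.03, against 0.25 with all arrays. The log2 changes of ALAS2, RETN and ATP2A1 were then -0.17, 0.09 and 0.15, against 0.24, 0.39 and 0.43 with all arrays.

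**Figure D3:**
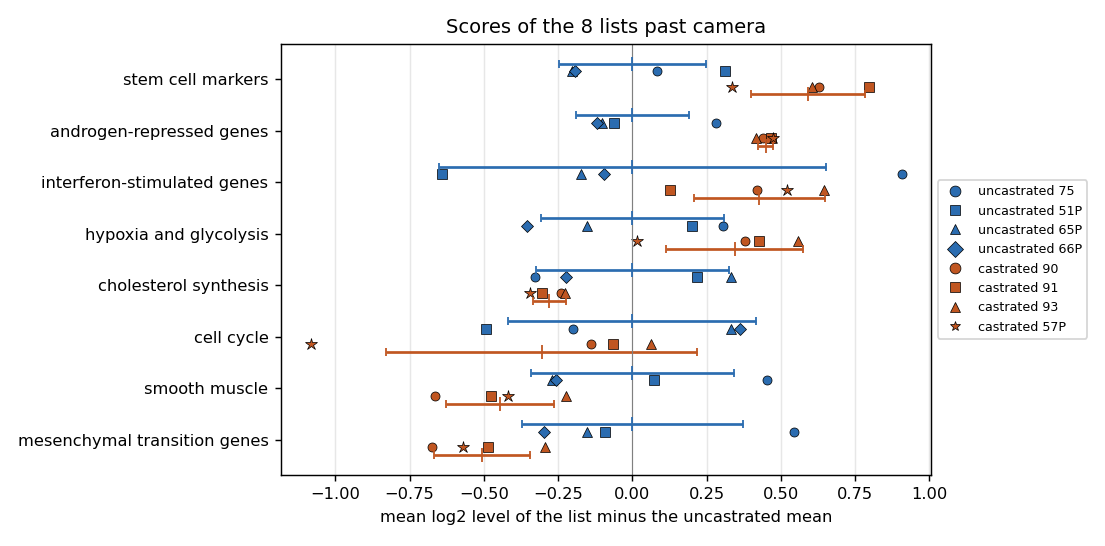
Mean log2 level of each list past camera, minus the mean of the uncastrated arrays (horizontal axis), with 1 point per array (blue, uncastrated; orange, castrated) and bars for mean ± SD of each group (n = 4). The cell cycle score of castrated 57P lies far to the left of the others, and the interferon score of uncastrated 75 is the highest of the 8.

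A score per tumour, the mean log2 level over a list, gave a comparison that needs no model of the spread but takes the tumours as independent. If castrated 90, 91 and 93 were 1 tumour, these p-values would not apply. By an exact two-sided permutation test over all 70 assignments, 4 lists reached 0.0286, the smallest p that 4 against 4 allows. The androgen-repressed score was 4.73 ± 0.19 in uncastrated and 5.18 ± 0.03 in castrated tumours (SD, n = 4, exact p = 0.0286). The stem cell score was 5.22 ± 0.25 and 5.81 ± 0.19, and the growth factor receptor score 6.45 ± 0.12 and 6.80 ± 0.14 (SD, n = 4, exact p = 0.0286 each). The growth factor list had a mean log2 change of 0.36 but a median of 0.11, and holds KIT, with a log2 change of 5.04. The fatty acid synthesis score went down, from 7.88 ± 0.15 to 7.60 ± 0.22 (SD, n = 4, exact p = 0.0286). It was 7.28 in castrated 57P and 7.65 to 7.74 in the other castrated tumours. Without 57P the score difference was -0.18, against -0.28 with all arrays. After Benjamini-Hochberg adjustment over 28 lists the smallest value was 0.2, so 0 lists passed. The number at an unadjusted exact p under 0.05 fell to 1 without uncastrated 65P or castrated 91, and to 2 without uncastrated 51P, castrated 90, castrated 93 or castrated 57P. Part of this drop reflects a coarser test, since fewer assignments exist with an array left out. Without 57P the androgen-repressed and stem cell scores did not overlap between groups, yet each had an exact p of 0.0571.

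For some lists the median, mean and camera direction differed in sign. The fibroblast list had a median log2 change of 0.04 and a mean of -0.34, the nuclear receptor list 0.05 and -0.03, the neuroendocrine list 0.06 and -0.07, the apoptosis list -0.13 and 0.08, and oxidative phosphorylation -0.01 and 0.02. Basal epithelium had a median of 0.06 and a mean of 0.10 with a downward camera direction.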

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

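Chosen only after the results were seen were the test of cells other than prostate cells, the test of castration as the reason for low prostate genes, the test of a batch shared by titles without suffix, and the test of a compression of 57P that keeps the order of genes. Castrated 57P and a few other tumours held values far from the other 3 of their group for genes of several kinds. In 57P, FOXQ1 was at 6.66 (log2 intensity; 8.24 to 8.30 in the other castrated tumours), GSPT2 at 4.64 (6.73 to 6.85), TKTL1 at 5.82 (2.55 to 2.95), ANKRD1 at 4.43 (2.64 to 2.65) and SYNE1 at 7.96 (5.37 to 5.78). The nuclear receptor RORA was at 6.10 there, NR3C1 at 8.99, the lipid synthesis genes SQLE, ACSL4 and ACLY at 7.28, 3.86 and 9.58, and the integrin ITGA2 at 7.19, all below the other castrated tumours. TNNI2, ALAS2 and KLK2 were above them, at 6.29, 6.56 and 5.69. Uncastrated 51P stood apart in GSPT2 (4.50), MSN (9.36), ANKRD37 (6.62) and DST (9.68), uncastrated 75 in EGLN3 (9.55) and ITGB2 (7.43), and castrated 93 in ACKR3 (5.96), RDH5 (3.70), ELF3 (8.71) and AXL (8.40). Of 272 groups of 4 values 48 held such a value, 33 of them that of 57P, where chance gives about 1 in 20 groups.

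List scores of 57P were lower than in the other castrated tumours for nuclear receptors (6.26), the unfolded protein list (8.25), epithelial markers (9.65), growth factor receptors (6.59), Wnt genes (5.62) and apoptosis regulators (7.13). They were higher there for neuroendocrine markers (5.21), skeletal muscle (4.53), endothelium (4.85), macrophages (4.89), erythrocytes (5.54) and adipocytes (4.88). Other scores far from their group were the androgen-repressed score of uncastrated 75 (5.02), its erythrocyte score (5.49), the neuroendocrine score of uncastrated 51P (5.19) and the oxidative phosphorylation score of castrated 91 (10.1). The 57P array also differed in its quartiles of intensity (10.6, 26.5 and 68.3), the SD of its log2 values (2.05), its bioB spike (791), its polyA spike (76.0) and its mean correlation with other arrays (0.919). The mean correlation of uncastrated 65P, 0.957, was below those of the other uncastrated arrays.

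Prostate luminal genes such as FOLH1 and HOXB13 had low intensities in these tumours labelled LNCaP. Some lung epithelial genes such as NAPSA had high ones in uncastrated tumours and castrated 57P. Against 10000 random lists the prostate list lay at the 16.9th to 42.3rd percentile (42.33 the highest on any array) and the lung list between 52.8 and 99.3, but intensities of different probe sets depend on probe affinity, so these ranks do not show which cells gave the RNA. Scrambled gene names are argued against by abundant genes at percentile 100 on all arrays. Weak arrays are not excluded, because the percentile is taken within each array and 57P and 65P reached it too. The prostate list score on the same probe sets was 0.46 higher in castrated tumours, without overlap between the groups. This argues only against lower levels of the list as a whole in castrated than in uncastrated tumours. A loss before passage cannot be judged, since per the labels regrown tumours could be passaged in intact hosts too. STEAP1 (5.21 to 7.44) and STEAP2 (4.90 to 6.60) carried much of the difference, and SLC45A3 and AMACR had lower means in castrated tumours. KLK2 was at 4.58 to 4.64 in castrated 90, 91 and 93, 4.65 to 4.86 in uncastrated tumours and 5.69 in castrated 57P. The breast list score was 0.51 higher in castrated tumours as well, so a rise was not special to prostate genes. For the low prostate genes, RNA from cells other than prostate luminal cells cannot be told apart from a line that has lost these genes or from weak probe sets. Levels of different genes decide none of these. Lost genes or weak probe sets would not account for the high lung genes such as NAPSA. Of the 14 prostate genes 11 also belong to the hormone lists.

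Castrated 57P stood apart from castrated 90, 91 and 93. At 67.6% of the 1711 genes called without it, 57P lay nearer the uncastrated mean, within the range of left-out uncastrated arrays (60.1% to 92.2%) and above that of left-out castrated ones (0.346% to 6.82%). A wrong group label of 57P stays open. KIT was at 9.04 there (2.54 to 5.78 in uncastrated tumours) and TNFSF10 at 8.01. MSN was at 5.85 (9.36 to 10.5 in uncastrated tumours). These values lay on the castrated side, but the genes were named because their groups, with 57P as castrated, did not overlap. They therefore cannot weigh against a wrong label. Whether compression adds to the distance of 57P cannot be told. Over 4944 brighter genes its rank correlations with castrated arrays ran from 0.707 to 0.749, the highest lying above the lowest pair of other arrays (0.721). That bar is loose, because it covers pairs across groups, and the highest rank correlation of 57P with an uncastrated array was 0.841. As the only difference, a compression that keeps the order of genes is argued against by 55 genes, such as SCGB3A2, above the 75th percentile on 57P and below the median on 90, 91 and 93, against 0 to 4 for each other array within its group.

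Castrated 90, 91 and 93 were close together, with 4 to 66 of the brighter genes at least 2-fold apart between 2 of them, against 64 to 831 for other pairs without 57P. They could be 1 tumour measured 3 times, which cannot be told apart from similar tumours because no array is known to be a repeat. A batch shared by titles without suffix also cannot be told apart, because the order depends on the features used. Over genes, array 75 had a mean correlation of 0.968 with them and 0.975 with the other uncastrated arrays, and over all probe sets 0.973 and 0.970. Its median absolute log2 difference over probe sets was 0.22 to 0.23 from them and 0.27 to 0.29 from the other uncastrated arrays.

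For the count of changed genes chance can be excluded only if the 8 arrays are independent tumours: the real split gave 243 genes and was the only 1 of 35 to give as many, the smallest share possible, the highest other split giving 45. If castrated 90, 91 and 93 were 1 tumour these splits would not apply, and with them averaged 0 genes passed. That other split set titles without the suffix P against titles with it. For the number of lists past camera chance cannot be excluded, since 11 of the 35 splits gave 8 or more lists, and the highest other split gave 11.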

How the results depend on the processing

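Chosen only after the data were seen were averaging castrated 90, 91 and 93, leaving out 57P and 65P together, and the list tests within each title suffix. The 36 named genes past the threshold kept their direction in each of the alternatives run. Their groups did not overlap, so leaving out, averaging, weighting or blocking arrays could not reverse a direction. Only rescaling of arrays, other handling of probe sets or moving tumour 93 could have done so. The number of changed genes, 243, was 22 to 1711 with single arrays left out, 3766 with array weights, 554 at adjusted p under 0.10, 2567 at unadjusted p under 0.05, 7527 within titles with the suffix P and 823 within titles without it. It was 1 with tumour 93 put with the uncastrated tumours, 0 with 90, 91 and 93 averaged (limma; 1532 at unadjusted p under 0.05), which leaves fewer samples, and 1251 without 57P and 65P. Array weights were 0.0907 for 57P and 2.41 to 4.31 for 90, 91 and 93. Centring on the 75th percentile moved the median log2 change of all genes from 0.04 to 0.14 and gave 150 higher and 108 lower genes, 41.9% lower against 64.2%.

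The 8 lists past camera became 1 to 8 with single arrays left out, 3 with the suffix as a block, 4 with tumour 93 moved, 0 with an estimated correlation, 2 with fry, 5 with 90, 91 and 93 averaged and 5 without 57P and 65P. The 4 list scores at exact p under 0.05 became 1 to 4 with single arrays left out, where the exact test is coarser. They became 7 after a further quantile normalization and 2 with probe sets averaged. Directions reversed for neuroendocrine markers among genes above the median level (-0.50) and for NR3C1 within the suffix P (-1.33), where 57P is the lone castrated array. Within titles without the suffix, where 75 is the lone uncastrated array, the sign was the other one for cell cycle (0.078), oxidative phosphorylation (0.21), interferon (-0.20), fibroblast (-0.27), macrophage (-0.25) and erythrocyte (-0.26), and so it was without 57P and 65P for cell cycle (0.0079). A further 94 sign changes were of results called in neither setting, such as EGLN3 (to -0.40) and ALAS2 (to -0.70). The cause was not tested. With single arrays left out, lists lost 25 calls and gained 1, and named genes lost 109 and gained 27. In the remaining alternatives lists lost 51 and gained 14, and named genes lost 107 and gained 104. No paired analysis was possible because the groups share no replicate numbers. Signal over background could not be judged for dim genes, as no detection calls were used.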

Other observations

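Both lists in this part were chosen only after their falling genes had been seen, and the tests without those genes only after the values of the whole lists had been seen. Several genes induced by the coactivators YAP and TAZ were lower in castrated tumours. Of 21 measured 7 fell (ANKRD1, RBMS3, CRIM1, AXL, TGFB2, AJUBA and PTPN14), 0 rose and 18 had a lower mean. CRIM1 fell by 2.42 on the log2 scale and AJUBA, a LIM domain gene, fell by 1.94 (limma adjusted p = 0.0117 and 0.0149). CCN2 and CCN1 had log2 changes of -1.76 and -1.68 without passing (limma adjusted p = 0.103 and 0.0911). IGFBP3 went the other way, with a log2 change of 2.18 (limma adjusted p = 0.0585). The median log2 change was -0.99, and -1.03 without 57P. The score was 8.28 ± 0.29 in uncastrated and 7.08 ± 0.14 in castrated tumours (SD, n = 4, exact p = 0.0286, the smallest possible). The 7 falls had been seen before the list was made, so tests of the whole list (camera adjusted p = 1.31e-12, and 0.0127 with an estimated correlation) only restate them. Without any gene past the threshold or named before, 10 of the 12 remaining members had a lower mean, with a median log2 change of -0.61, and -0.36 without 57P. For these the camera adjusted p was 0.0222 with an estimated correlation, but 0.181 without 57P, and 0.0799 with IGFBP3 and CCN1 kept. Which members were left depended on their own changes, so whether the set is lower cannot be told.

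Several genes of actomyosin and focal adhesions were lower as well. Of 21 measured 5 fell and 15 had a lower mean. The actin bundler PALLD fell by 1.94, MYLK fell by 1.90, the non-muscle myosin gene MYH9 fell by 1.26, the adhesion gene PXN fell by 1.19 and MYL9 fell by 1.06 on the log2 scale. TPM4 and PDLIM7 went the other way, with log2 changes of 0.82 and 0.48 without passing. The score was 8.58 ± 0.22 and 8.06 ± 0.16 (SD, n = 4, exact p = 0.0286). All 5 falls had been seen before this list was drawn up, so tests of the whole list (camera adjusted p = 2.44e-08, and 0.0342 with an estimated correlation) only restate them. Among the 16 remaining members 10 had a lower mean, with a median log2 change of -0.20, and whether the set is lower cannot be told (camera adjusted p = 0.207 with an estimated correlation).

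The prostate list score was 5.17 ± 0.19 in uncastrated and 5.63 ± 0.06 in castrated tumours (SD, n = 4, exact p = 0.0286, adjusted p = 0.0857 over 9 lists). A rise was not special to this list: the breast score differed by 0.51, with the same exact and adjusted p. The urothelium score differed by 0.44 (exact p = 0.0571). The lung score went furthest the other way, by -0.55 (6.94 ± 0.33 and 6.40 ± 1.08, SD, n = 4, exact p = 0.4). It was 7.96 in castrated 57P and 5.54 to 6.20 in the other castrated tumours. Thyroid (-0.20, exact p = 0.0571) and abundant genes (-0.18, exact p = 0.0286) were also among the lists that went the other way. Chosen after their values were seen, STEAP1 was at 5.21 ± 0.82 and 7.44 ± 0.94, and STEAP2 at 4.90 ± 0.90 and 6.60 ± 0.79 (log2 intensity, SD, n = 4). The lists of liver, colon, thyroid, breast, urothelium and kidney lay at intensity percentiles, which depend on probe affinity, of 22.9 to 30.8, 3.83 to 13.3, 40.7 to 69.1, 11.1 to 45.7, 10.5 to 22.0 and 16.2 to 30.6 on the 8 arrays.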
